A study of Mus musculus with 7 samples.

How the data were processed

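RNA from mouse quadriceps was profiled in 7 libraries, 4 of the AAV8-Null group and 3 of the AAV8-IGFBP1 group, and each library was assigned to its group by its title. Per the labels' protocols, total RNA was isolated with the RNeasy Mini Kit and libraries were made with the Universal Plus mRNA-Seq kit with NuQuant. The authors deposited 1 table of estimated counts per gene symbol, made from the reads with the tools named below per the submitters' processing notes, with 53819 genes and a column per library. The values need not be whole, and 5617 to 6277 values per library were not (tolerance 1e-06). Per the submitters' processing notes, which give no roles or order, the tools were cutadapt 3.4, Trim Galore 0.6.7, STAR 2.7.9a, Salmon 1.10.1 and R 4.2.2, and the genome build was GRCm39. The annotation release and the strand setting were not given in the sources used here, so overlapping and antisense genes could share reads. Symbols such as Metazoa_SRP, 7SK and the histocompatibility and Hspa1a and Hspa1b genes cover near-identical copies whose reads the counting could split. Genome positions are not given because the annotation at hand is of another build than that of the counts.

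The estimated counts were rounded to whole numbers before testing. Library totals ranged from 38947493 to 51210391 counts, and a count of 0 allows up to 3 counts of the total, a floor of 0.0586 to 0.0770 CPM per library; this covers counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 22.2 to 60.0), so none was taken for a repeat deposit of the same library. Separate libraries of one mouse would also differ by more than sampling noise, so this leaves open whether the libraries came from separate mice. CPM values are counts relative to library totals scaled by edgeR's TMM factors, from edgeR's cpm function, and log2 CPM values use a prior count of 2.

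The main test was edgeR 4.0.16 (R 4.3.3): filterByExpr with its defaults (minimum count 10, minimum total count 15), TMM scaling, estimateDisp, glmQLFit with robust set to TRUE, and glmQLFTest on group alone, with Benjamini-Hochberg adjustment over the 14935 genes kept and a threshold of 0.05. All adjusted p-values of single genes are from this test unless another tool is named. Standard errors of log2 fold changes are approximate, the size of the log2 fold change divided by the square root of the F statistic. The design, the alternatives, the gene lists and the naming rule were fixed before the data were examined. The 53 gene lists covered muscle physiology, signalling and the cell types that muscle can hold. The 52 lists with at least 5 tested members were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the lists. Of 52 lists, camera called 23 (8 higher and 15 lower) with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.351 and 4 lists had an unadjusted p under 0.05. fry called 1 list in a direction and 20 for change in either direction. The list level is the mean over members of log2 CPM centred over the 7 libraries. Single values per library were compared with an exact permutation test of the difference of means over all 35 splits of 7 libraries into 4 and 3 (two-sided, smallest p 0.0286). These exact permutation p-values were not adjusted over the values or lists tested.

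The text names Igfbp1 and the measured IGF axis genes; the 12 changed genes with the highest and the 12 with the lowest log2 fold change among those with a mean log2 CPM of at least 1, groups that did not overlap and a symbol that is not a predicted or clone name; up to 4 members per described list with the lowest unadjusted p; and genes that a check or a count of 5 or fewer singles out. Genes named outside this rule are said to have been picked after their values were seen. The choice of lists to describe was made after their results were seen.

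The steps were tested on 10 sets of simulated counts for this comparison, with a median of 14835 genes tested and 200 genes changed by known folds. The gene test recovered 37.2% of genes changed 1.5-fold, 67.6% of those changed 2-fold, 82.2% at 3-fold and 89.2% at 4-fold, and 8.58% of all calls were unchanged genes. A list moved 1.3-fold was called in 10 of 10 sets and 0 of 500 unchanged lists were called; genes were simulated as independent, which real genes are not.

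The alternatives tried were DESeq2 size factors and upper-quartile scaling in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom without and with quality weights, no count filter and a stricter one, robust FALSE, the older edgeR method, a threshold of 0.1, the replicate number as a block, scaling without mitochondrial and the 10 most abundant genes, and each library left out in turn. Added after the data were seen were the adipocyte, tenocyte and slow fibre levels as covariates and a fit without both libraries numbered 3. All 7 libraries entered every comparison. Some genes that the naming rule picks are not reported here.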

Results

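RNA from the quadriceps, the large thigh muscle, was sequenced in 7 libraries from male C57BL/6J mice, an inbred laboratory strain. The mice had received 200 µl of an AAV8 vector, an adeno-associated virus that reaches mainly the liver, through the tail vein at 8 weeks of age, and the muscle was taken 54 days later. The vector was AAV8-Alb-Null, the vector control, in 4 libraries (AAV8-Null) and AAV8-Alb-IGFBP1 in 3 libraries (AAV8-IGFBP1). IGFBP1 is a secreted protein made mainly by the liver that binds insulin-like growth factors (IGFs). The labels number the replicates within each group but do not state that each library came from a separate mouse, so the p-values measure only the spread between these samples, which may be technical. The library totals were 49180219, 51210391, 38947493 and 42557954 estimated counts for AAV8-Null replicates 1 to 4 and 45717839, 39927146 and 46197214 for AAV8-IGFBP1 replicates 1 to 3, and did not differ between the groups beyond their spread (exact permutation p = 0.714, two-sided). On the first principal component, which held 29.3% of the variance, AAV8-IGFBP1 replicate 2 lay at 36.9 and the other 6 libraries between -17.3 and 5.94. Rn18s, an 18S ribosomal RNA gene, took 0.840 ± 0.329% (SD, n = 4) of the counts in AAV8-Null and 1.63 ± 0.606% (SD, n = 3) in AAV8-IGFBP1 (exact permutation p = 0.0857).

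The comparison asked what a liver-directed IGFBP1 vector does to gene expression in muscle. In the AAV8-IGFBP1 muscle, Socs2, which encodes a feedback inhibitor of growth hormone signalling, was 3.57-fold higher, the clock-controlled transcription factor gene Dbp 3.74-fold higher and Irf7, a transcription factor gene of the interferon response, 3.56-fold higher. Bcl6, which encodes a transcriptional repressor, fell 1.99-fold, Tagln, an actin-binding protein gene of smooth muscle, 2.14-fold, and the basement membrane collagen gene Col15a1 1.68-fold. Of 14935 genes tested, 87 changed by edgeR's quasi-likelihood test at an adjusted p under 0.05, 58 of them higher and 29 lower in AAV8-IGFBP1. All 87 had every AAV8-IGFBP1 library on one side of every AAV8-Null library, as had 12.3% of all genes tested, where chance gives 5.71%. The count of 87 was 14 without AAV8-Null replicate 1, 44 without AAV8-Null replicate 3, and 27, 30 and 49 without AAV8-IGFBP1 replicate 1, 2 and 3. Of the 34 changed genes picked by the naming rule, Socs2, Dbp, Irf7, Bcl6, Tagln, Col15a1 and Dusp7 stayed past the test without each of the 7 libraries in turn. The other 27 lost it in at least 1 of these fits, and the count of the 34 that stayed was 8 without AAV8-Null replicate 1, 20 without replicate 2, 20 without replicate 3 and 22 without replicate 4, and 13, 14 and 18 without AAV8-IGFBP1 replicate 1, 2 and 3.

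Igfbp1 transcripts were present in the muscle of all 3 AAV8-IGFBP1 libraries, at 202, 1425 and 142 counts (4.39, 34.5 and 3.14 CPM for replicates 1, 2 and 3, where CPM is the count relative to the scaled library total). AAV8-Null replicate 4 had 8 counts (0.195 CPM) and the other 3 AAV8-Null libraries had 0, which allows up to 0.0610, 0.0586 and 0.0770 CPM in replicates 1, 2 and 3 from counting error alone. The AAV8-IGFBP1 libraries all lay above the AAV8-Null libraries (exact permutation p = 0.0286, two-sided, the smallest that 35 splits can give). The fitted log2 fold change was 8.21 (SE 1.54), with an edgeR adjusted p of 0.0691 that missed the threshold. DESeq2 gave an adjusted p of 0.0128, and the adjusted p ran from 0.00727 to 0.464 over all alternatives tried. Without AAV8-IGFBP1 replicate 2, the library with the most Igfbp1 counts, Igfbp1 passed the test (log2 fold change 6.33, edgeR adjusted p = 0.00727), and without AAV8-Null replicate 4, which left the control group at 0 counts, the fitted log2 fold change was 12.30 (edgeR adjusted p = 0.432).

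Genes of the IGF axis, meaning IGFs, their receptors, binding proteins and downstream signalling, had a log2 fold change above 0 in 19 of 27 tested members. Socs2 went from 8.08 ± 1.78 to 28.8 ± 2.75 CPM (SD, n = 4 and 3; log2 fold change 1.83, SE 0.16, edgeR adjusted p = 0.00679). Igfals, which encodes the acid-labile subunit of the circulating IGF complex, went from 3.64 ± 0.309 to 8.66 ± 1.61 CPM (log2 fold change 1.24, SE 0.14, edgeR adjusted p = 0.00985). Igfbp5, a further IGF-binding protein gene, went from 859 ± 130 to 1434 ± 62.8 CPM (log2 fold change 0.74, SE 0.11, edgeR adjusted p = 0.0295). These 3 members rose, the other 24 did not pass the test, and adjusted over the list alone 8 were higher and 1 lower. Pappa, a protease gene whose product cleaves IGF-binding proteins, had a log2 fold change of 1.26 (edgeR adjusted p = 0.0644), Pik3r1 of 0.67 (0.0737) and Igf1 of 0.60 (0.177), and none of them passed edgeR's test. All 3 passed with DESeq2 (adjusted p 4.55e-06, 0.000159 and 0.00957; highest over all alternatives 0.177, 0.385 and 0.632). DESeq2 called 6 members of the list, all higher. Of the 8 members below 0, Irs2, an insulin receptor substrate gene, had a log2 fold change of -1.52 (SE 0.60, edgeR adjusted p = 0.386), Igfbp4 of -0.47 (0.397) and Igf2r of -0.20 (0.246). Irs2 lay at 159 CPM in AAV8-Null replicate 3 and at 37.0 to 48.8 CPM in the other AAV8-Null libraries. In AAV8-IGFBP1 it lay at 22.99 to 27.89 CPM, below every AAV8-Null library, so the groups did not overlap for Irs2 either. Its log2 fold change ran from -1.74 to -0.80 with 1 library left out. Igf1r (0.19) and the insulin receptor gene Insr (-0.01) had edgeR adjusted p-values of 0.650 and 0.968. The list as a whole was called higher by limma's camera (adjusted p = 7.43e-05, median log2 fold change 0.13), and the call was lost with an estimated correlation (adjusted p = 0.491 with an estimated correlation). The list levels overlapped between the groups (exact permutation p = 0.0857), and the median was 0.05 with the slow fibre level as covariate, a fit added after the data were seen. Igfals fell short of the threshold without AAV8-Null replicate 1 (edgeR adjusted p = 0.0526). Igfbp5 did so without AAV8-Null replicate 1 (0.0840) or AAV8-IGFBP1 replicate 1 (0.0863), 2 (0.0830) or 3 (0.0728).

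**Figure D1:**
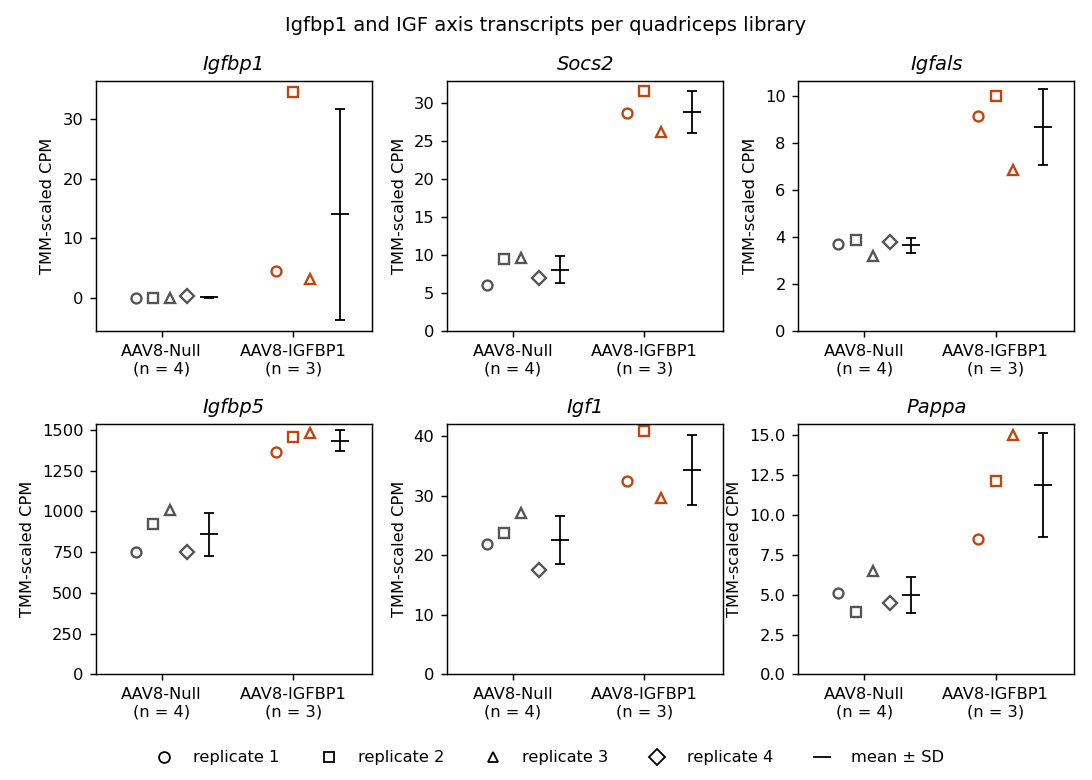
TMM-scaled CPM (y axes) of Igfbp1 and 5 IGF axis genes in the 4 AAV8-Null and 3 AAV8-IGFBP1 libraries; symbols mark replicates and bars the mean ± SD. The Socs2 means were 8.08 and 28.8 CPM, and for each of the 6 genes all AAV8-IGFBP1 libraries lay above all AAV8-Null libraries.

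Circadian clock genes moved in both directions. Ciart (log2 fold change 2.11, SE 0.33, edgeR adjusted p = 0.0393), Dbp (1.90, SE 0.18, 0.0103), Bhlhe40 (0.85, SE 0.11, 0.0179), Per3 (0.85, SE 0.12, 0.0242) and Bhlhe41 (0.56, SE 0.08, 0.0269) rose. Arntl, which encodes the clock activator BMAL1 (-1.03, SE 0.16, edgeR adjusted p = 0.0423), and its partner gene Npas2 (-2.15, SE 0.32, 0.0307; picked after its values were seen) fell. These were 7 of 20 tested members, and adjusted over the list alone 9 were higher and 5 lower. Dbp went from 22.0 ± 5.13 to 82.1 ± 5.20 CPM (SD, n = 4 and 3). The list was called higher by limma's camera (adjusted p = 0.000474, median log2 fold change 0.36), with an adjusted p = 0.491 with an estimated correlation and an exact permutation p of 0.0857 for the list level. With the slow fibre level as covariate, a fit added after the data were seen, the median was 0.13. Grouped, after the values were seen, by their textbook place in the clock, all 11 tested genes of the arm with Dbp had a log2 fold change above 0 and all 5 of the arm with Arntl one below 0. The other 4 tested members, among them Usp2 (0.50), Rora (0.27) and Cry2 (0.23), were put in neither arm, a choice also made after the values were seen. The unnamed member of these 4 had a log2 fold change below 0. Of all 20 tested members, 14 lay above 0 and 6 below. The sampling time of day was not given in the sources used here. Dbp stayed past the test without each library in turn. The other 6 genes lost it without AAV8-Null replicate 1 and without AAV8-IGFBP1 replicate 3, and each also without others: Ciart without AAV8-Null replicate 2 or 4 or AAV8-IGFBP1 replicate 1 (edgeR adjusted p over its lost fits 0.0758 to 0.138), Per3 without AAV8-IGFBP1 replicate 1 or 2 (0.0550 to 0.0863), and Arntl without AAV8-Null replicate 3 or 4 or AAV8-IGFBP1 replicate 1 (0.0567 to 0.161). Bhlhe40 and Npas2 also lost it without AAV8-Null replicate 3 or AAV8-IGFBP1 replicate 1 or 2 (edgeR adjusted p 0.0526 to 0.0747 and 0.0594 to 0.0906), and Bhlhe41 without AAV8-Null replicate 2 or 3 or AAV8-IGFBP1 replicate 2 (0.0524 to 0.0895).

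**Figure D2:**
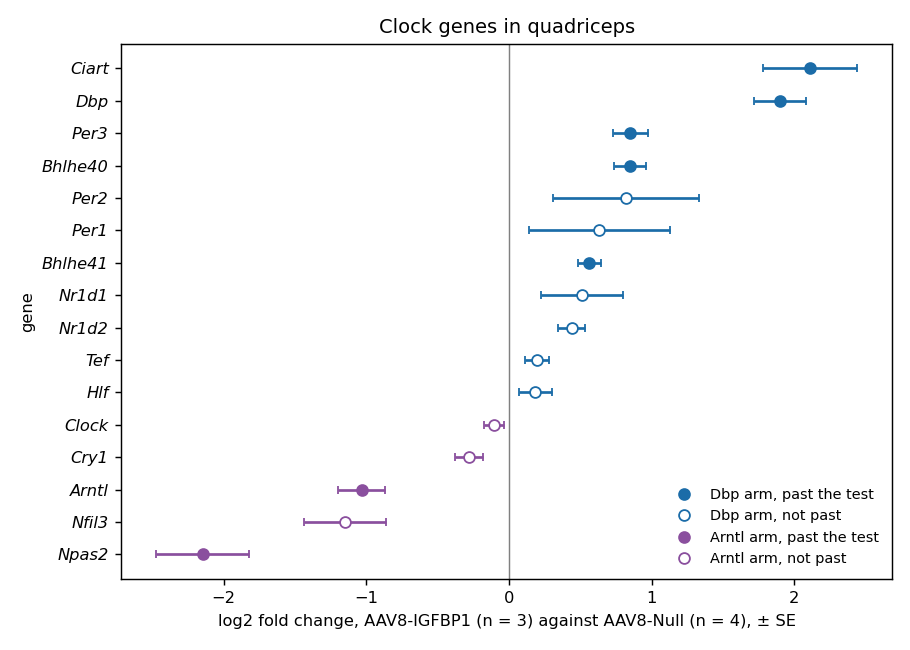
Log2 fold change of 16 clock genes in AAV8-IGFBP1 (n = 3) against AAV8-Null (n = 4), with the SE as bars; filled points passed edgeR's test at an adjusted p under 0.05. Genes of the Dbp arm lie above 0, from Hlf at 0.19 to Ciart at 2.11, and genes of the Arntl arm below 0, from Clock at -0.10 to Npas2 at -2.15.

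All 35 tested interferon response genes had a log2 fold change above 0, with a median of 0.71. Irf7 (log2 fold change 1.83, SE 0.14, edgeR adjusted p = 0.00296), Ifit3 (1.07, SE 0.17, 0.0336) and Bst2 (0.79, SE 0.12, 0.0336), both encoding antiviral proteins, rose. Irf7 went from 2.28 ± 0.403 to 8.08 ± 0.573 CPM (SD, n = 4 and 3). Adjusted over the list alone, 12 members were higher. limma's camera called the list higher (adjusted p = 5.64e-15), with an adjusted p = 0.491 with an estimated correlation. The mean list level lay at 0.28, 0.74 and 0.08 in AAV8-IGFBP1 replicates 1, 2 and 3 and between -0.41 and -0.22 in AAV8-Null (exact permutation p = 0.0286, the smallest that can be given), and the median log2 fold change without AAV8-IGFBP1 replicate 2 was 0.44. Of 19 antigen presentation genes, all had a log2 fold change above 0 (median 0.65) and H2-Q6, a major histocompatibility class I gene, rose (1.47, SE 0.24, edgeR adjusted p = 0.0415); reads of H2-Q6 and its near-identical copy H2-Q7 (1.40, edgeR adjusted p = 0.0644) may not be told apart, so both are uncertain. Adjusted over the list alone, 3 were higher, and limma's camera gave an adjusted p of 6.14e-07, with an adjusted p = 0.688 with an estimated correlation. The antigen presentation levels overlapped between the groups (exact permutation p = 0.0571), and the median without AAV8-IGFBP1 replicate 2 was 0.14. That library also had the highest adipocyte marker level, 1.86 against -0.96 to 0.23 in the other 6 libraries. With that level as covariate, a fit added after the data were seen, the interferon and antigen presentation medians were 0.43 and 0.18. Irf7 stayed past the test without each library in turn. Ifit3 stayed past it only without AAV8-IGFBP1 replicate 3 (edgeR adjusted p without any 1 of the other 6 libraries 0.0636 to 0.0906), H2-Q6 only without AAV8-Null replicate 1 (0.0679 to 0.128), and Bst2 lost it without each of the 7 (0.0501 to 0.122).

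Of 39 tested collagen and extracellular matrix genes, 2 fell. The collagen genes Col5a3 (log2 fold change -1.15, SE 0.17, edgeR adjusted p = 0.0369) and Col15a1 (-0.75, SE 0.08, 0.00902) fell, and 35 members had a log2 fold change below 0 (median -0.44). The elastin gene Eln (-1.09, edgeR adjusted p = 0.0755) and Col5a1 (-0.82, 0.0816) did not pass the test; adjusted over the list alone, 11 members were lower. limma's camera called the list lower (adjusted p = 1.99e-13), with an adjusted p = 0.565 with an estimated correlation, and the median without AAV8-IGFBP1 replicate 1 was -0.72. The list levels overlapped between the groups (exact permutation p = 0.114), as did those of the fibroblast markers below (0.171). In fits added after the data were seen, the collagen median was -0.16 without both libraries numbered 3, -0.22 with the tenocyte marker level as covariate and -0.99 with the slow fibre level as covariate. Of 21 fibro-adipogenic progenitor and fibroblast markers, Col15a1 fell, 3 were lower adjusted over the list alone, and camera gave an adjusted p of 5.19e-05, with an adjusted p = 0.698 with an estimated correlation. Their median of -0.34 became -0.19 without AAV8-Null replicate 2, -0.22 without AAV8-IGFBP1 replicate 2 and -0.16 without AAV8-IGFBP1 replicate 3, and -0.17 and -0.66 with the tenocyte and slow fibre levels as covariates. That call was lost without both libraries numbered 3 (adjusted p = 0.153, median -0.15). Tenocyte markers, which tell how much tendon a sample holds, had a mean level of 0.99 in AAV8-Null replicate 3 and -1.33 in AAV8-IGFBP1 replicate 3, the extremes of the 7 libraries. Of 16 tenocyte markers 0 passed the test by edgeR, DESeq2 or limma-voom, and adjusted over the list alone 0 passed. The 1 marker with an unadjusted edgeR p under 0.05 was higher in AAV8-IGFBP1, while 14 of the 16 had a log2 fold change below 0. The tenocyte list was called lower by camera (median -0.41, adjusted p = 0.0289; adjusted p = 0.805 with an estimated correlation; exact permutation p of the levels 0.371). That call was lost without AAV8-Null replicate 3 (adjusted p = 0.172, median -0.18) or AAV8-IGFBP1 replicate 3 (adjusted p = 0.994, median -0.06), and the median was -1.05 without AAV8-IGFBP1 replicate 1 and -1.61 with the slow fibre level as covariate. Col15a1 stayed past the gene test without each library in turn, and Col5a3 lost it without AAV8-Null replicate 1, 2 or 4 or AAV8-IGFBP1 replicate 1 or 2 (edgeR adjusted p 0.0646 to 0.119).

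Of 16 tested markers of satellite cells, the muscle stem cells, 1 fell. Sdc4, a cell surface proteoglycan gene, fell from 28.9 ± 5.15 to 14.6 ± 0.585 CPM (SD, n = 4 and 3; log2 fold change -0.99, SE 0.13, edgeR adjusted p = 0.0167). Pax7, the transcription factor gene that defines these cells (-0.93, edgeR adjusted p = 0.0637), and the receptor gene Fgfr4 (-1.10, 0.0670) did not pass the test over all genes. The log2 fold change was below 0 in 13 members (median -0.32) and above 0 in 3, among them the cadherin gene Cdh15 (0.22, edgeR adjusted p = 0.286), and adjusted over the list alone 5 were lower and 1 higher. limma's camera called the list lower with an adjusted p of 0.000180, with an adjusted p = 0.351 with an estimated correlation. This was the only list that fry, which tests whether members move one way on balance, called (adjusted p = 0.0362), and the list levels did not overlap between the groups (exact permutation p = 0.0286, the smallest that can be given). Levels of the interferon response, Schwann cell, myokine and glycogen metabolism lists gave the same exact permutation p. Camera did not call the glycogen metabolism list (adjusted p = 0.421), so such a separation is weak support. Of 16 smooth muscle and pericyte markers, Tagln fell (log2 fold change -1.10, SE 0.13, edgeR adjusted p = 0.00985) and the smooth muscle actin gene Acta2 had -1.20 (0.0764). Adjusted over the list alone 3 of these markers were lower; camera gave an adjusted p of 0.000981 (median -0.14), with an adjusted p = 0.491 with an estimated correlation, and the levels gave an exact permutation p of 0.0571. Tagln stayed past the test without each library in turn, and Sdc4 lost it without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 1, 2 or 3 (edgeR adjusted p 0.0525 to 0.0906).

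Slow fibre genes had lower values in AAV8-IGFBP1 with a wide spread. Of 16 tested members 15 had a log2 fold change below 0 and the median was -1.24, as for Tnnc1, which encodes troponin C of slow muscle (-1.71, SE 0.55, edgeR adjusted p = 0.311), and Myl2 (-1.39, SE 0.49, 0.341). By edgeR 0 slow fibre genes passed the test, 8 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0; adjusted over the list alone 0 passed. limma's camera called the list lower (adjusted p = 1.54e-08), with an adjusted p = 0.565 with an estimated correlation. The list level lay between -0.30 and 1.01 in AAV8-Null and between -1.23 and -0.01 in AAV8-IGFBP1 (exact permutation p = 0.0857). Fast fibre genes were not called (median 0.04, camera adjusted p = 0.165); without AAV8-Null replicate 2 or AAV8-IGFBP1 replicate 2 they were called higher (adjusted p = 0.00651 and 0.0376). In edgeR's test 0 of 20 fast fibre genes passed, adjusted over the list alone 0 passed, 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Myh4, the main fast myosin heavy chain gene, had a log2 fold change of 0.17 (SE 0.10, edgeR adjusted p = 0.551).

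**Figure D3:**
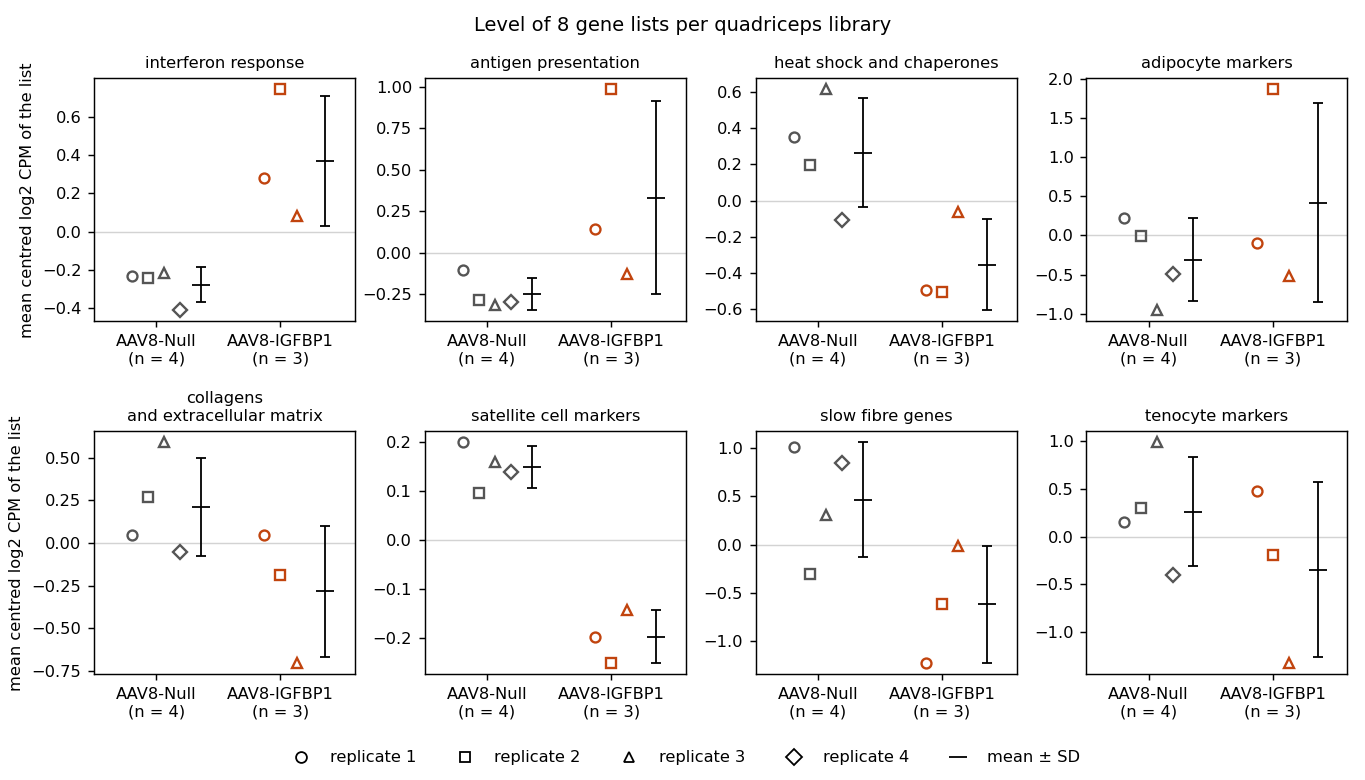
Mean level of 8 gene lists (log2 CPM of each gene centred over the 7 libraries, y axes) per library in AAV8-Null (n = 4) and AAV8-IGFBP1 (n = 3); symbols mark replicates and bars the mean ± SD. Interferon response levels lie between -0.41 and -0.22 in AAV8-Null and between 0.08 and 0.74 in AAV8-IGFBP1, while the adipocyte marker level of 1.86 belongs to AAV8-IGFBP1 replicate 2 alone.

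Of the lists of energy metabolism, 4 were called lower with small medians and no member past the test. Fatty acid uptake and oxidation genes (median -0.12, mean 0.02, camera adjusted p = 0.387, 0 of 32 with an unadjusted p under 0.05) and glycolysis and glucose uptake genes (median -0.07, 0.165) were not called. With 1 library left out, each list stayed uncalled in 6 of 7 fits. Their medians then ran from -0.19 to -0.05 and from -0.09 to -0.04. The lowest camera adjusted p over all alternatives was 0.00661 and 0.0201. All 15 mitochondrial DNA-encoded genes had a log2 fold change below 0 (median -0.20; mt-Rnr2 -0.49, edgeR adjusted p = 0.254), and mitochondrial transcripts took 17.37 ± 1.53% (SD, n = 4) of counts in AAV8-Null and 14.98 ± 0.425% (SD, n = 3) in AAV8-IGFBP1 (exact permutation p = 0.0857). Subunits of complex I (median -0.08), nuclear subunits of complexes II to V (-0.09) and enzymes of the TCA cycle (-0.13) were also called lower by limma's camera. The camera adjusted p-values of these 4 lists were 1.86e-05, 0.00728, 0.000361 and 0.000474; the adjusted p-values were 0.581, 0.805, 0.805 and 0.714 with an estimated correlation. In edgeR's test 0 of 15, 38, 40 and 20 members passed, adjusted over the list alone 0 passed, 5, 1, 3 and 2 had an unadjusted p under 0.05, DESeq2 called 1 mitochondrial DNA-encoded gene and 0 of the others, and limma-voom called 0. The complex I call was lost without AAV8-Null replicate 1 (adjusted p = 0.205) or 4 (0.104) or AAV8-IGFBP1 replicate 1 (0.0935) or 2 (0.433). The call of complexes II to V was lost without AAV8-Null replicate 1 (adjusted p = 0.0622) or AAV8-IGFBP1 replicate 2 (0.111). Without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 2 the median of complex I was -0.04 and that of complexes II to V -0.05. Without AAV8-IGFBP1 replicate 3 the medians of complex I, complexes II to V and the TCA cycle were -0.15, -0.18 and -0.21. The median of complexes II to V was also -0.14 without AAV8-Null replicate 2 or 3, and that of the TCA cycle was -0.08 without AAV8-IGFBP1 replicate 1. The list levels did not differ beyond their spread (exact permutation p = 0.0857 for mitochondrial DNA-encoded genes, 0.371 for complex I, 0.343 for complexes II to V and 0.257 for the TCA cycle). Slow fibre levels were 1.01, -0.30, 0.31 and 0.84 in AAV8-Null replicates 1 to 4 and -1.23, -0.62 and -0.01 in AAV8-IGFBP1 replicates 1 to 3. In the same order, levels of complexes II to V were 0.17, -0.07, -0.06 and 0.13, and -0.12, -0.15 and 0.10. With the slow fibre level as covariate, a fit added after the data were seen, the medians of complex I, complexes II to V and the TCA cycle were 0.07, 0.09 and 0.07, and that of the mitochondrial DNA-encoded genes was -0.03.

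Heat shock and chaperone genes all had a log2 fold change below 0 (21 of 21, median -0.38), among them the small heat shock protein genes Cryab (-0.66, SE 0.15, edgeR adjusted p = 0.124) and Hspb6 (-0.48, SE 0.12, 0.133). By edgeR 0 passed the test, 12 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 0; adjusted over the list alone 2 were lower. limma's camera gave an adjusted p of 3.55e-09, with an adjusted p = 0.505 with an estimated correlation. The list level gave an exact permutation p of 0.0857, and those of the next 2 lists 0.171 each. Of 23 immediate early genes, which respond within minutes to stimuli, 21 had a log2 fold change below 0 (median -0.64; Atf3 -1.43, SE 0.42, edgeR adjusted p = 0.247). With 1 library left out the value of Atf3 ran from -2.27 to -1.13. It stayed short of the test in 6 of these 7 fits and passed it in 2 of all 23 alternatives. By edgeR 0 immediate early genes passed, 4 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom called 0, and adjusted over the list alone 0 passed; camera gave an adjusted p of 0.000182, with an adjusted p = 0.706 with an estimated correlation. Their median was -0.32 without AAV8-Null replicate 2 and -0.40 without AAV8-IGFBP1 replicate 1. Cytosolic ribosomal protein genes were called higher as a list (77 of 78 above 0, median 0.08, camera adjusted p = 2.29e-08; adjusted p = 0.714 with an estimated correlation), and the median was 0.05 without AAV8-Null replicate 3 and 0.04 with the slow fibre level as covariate. Of the 78, edgeR called 0, 5 had an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and adjusted over the list alone 0 passed.

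Atrophy genes, the ubiquitin ligases and FoxO targets that rise in wasting muscle, were not called as a list (median 0.02, camera adjusted p = 0.599). Fbxo32, which encodes the ubiquitin ligase atrogin-1, went from 524 ± 64.2 to 351 ± 34.4 CPM (SD, n = 4 and 3; log2 fold change -0.58, SE 0.11, edgeR adjusted p = 0.0605). Eif4ebp1, a translation inhibitor gene, had a log2 fold change of 0.39 (edgeR adjusted p = 0.0737). By edgeR 0 of 29 atrophy genes passed, 7 had an unadjusted p under 0.05, DESeq2 called 4, limma-voom called 0, and adjusted over the list alone 2 were higher and 1 lower. Denervation and neuromuscular junction genes were not called (median -0.05, camera adjusted p = 0.929); by edgeR 0 of 24 passed, 4 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom called 0, and adjusted over the list alone 1 was higher, the junction gene Dok7 (0.37, edgeR adjusted p = 0.0670). Of 17 embryonic and regenerating muscle genes, H19, an imprinted noncoding RNA, fell from 400 ± 29.5 to 245 ± 39.2 CPM (log2 fold change -0.71, SE 0.11, edgeR adjusted p = 0.0307), 1 was higher and 1 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.929). H19 lost the test without AAV8-Null replicate 1, 2 or 3 or AAV8-IGFBP1 replicate 2 or 3 (edgeR adjusted p 0.0516 to 0.0895).

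Single members of other lists also rose. The calcium channel subunit gene Cacnb1 (log2 fold change 0.32, SE 0.05, edgeR adjusted p = 0.0417) rose among 25 excitation-contraction genes, of which 3 were higher adjusted over the list alone. That list was called higher (median 0.06, camera adjusted p = 0.00281; adjusted p = 0.714 with an estimated correlation), though not without AAV8-IGFBP1 replicate 3 (adjusted p = 0.109), and its median was 0.10 without AAV8-Null replicate 2 and 0.11 without AAV8-IGFBP1 replicate 2. The Wnt receptor gene Fzd4 (0.75, SE 0.09, edgeR adjusted p = 0.0103) and Dkk3 (0.83, SE 0.10, 0.0103) rose among 21 Wnt pathway genes, of which 2 were higher adjusted over the list alone, and the list was not called (camera adjusted p = 0.673). The talin gene Tln2 rose (0.46, SE 0.08, edgeR adjusted p = 0.0460) among 23 integrin and focal adhesion genes, of which 1 was higher and 2 lower adjusted over the list alone. Of these 23 genes 20 had a log2 fold change below 0 (median -0.08, camera adjusted p = 0.0155; adjusted p = 0.565 with an estimated correlation), the median was -0.14 without AAV8-IGFBP1 replicate 1, and the call was lost without AAV8-IGFBP1 replicate 2 (0.151). The antioxidant enzyme gene Gpx3 rose (0.73, SE 0.12, edgeR adjusted p = 0.0415) among 20 NRF2 targets, of which 1 was higher adjusted over the list alone, and the list was not called (camera adjusted p = 0.929). Of 18 genes for myokines and other secreted muscle factors, such as Erfe (-1.38, SE 0.32, edgeR adjusted p = 0.118) and Ostn (-0.48, SE 0.13, 0.166), 15 had a log2 fold change below 0. By edgeR 0 of them passed, 4 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom called 0, and adjusted over the list alone 2 were lower. Camera called that list lower (median -0.21, adjusted p = 0.0131; adjusted p = 0.491 with an estimated correlation), but not without AAV8-Null replicate 3 (0.0827, median -0.09) or AAV8-IGFBP1 replicate 2 (0.0512), and the median was -0.38 without AAV8-Null replicate 2 and -0.12 with the slow fibre level as covariate. Without AAV8-Null replicate 1, Fzd4 (edgeR adjusted p = 0.0526) and Dkk3 (0.0580) missed the threshold. Cacnb1 missed it without each of the 7 libraries (edgeR adjusted p 0.0595 to 0.159), Tln2 without any except AAV8-Null replicate 4 (0.0732 to 0.174) and Gpx3 without any except AAV8-IGFBP1 replicate 3 (0.0756 to 0.148).

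Outside the lists, Dusp7, which encodes a phosphatase of the ERK kinases (log2 fold change 0.98, SE 0.10, edgeR adjusted p = 0.00679), Zfp503 (1.09, SE 0.13, 0.00985), Prima1, which encodes the membrane anchor of acetylcholinesterase (1.48, SE 0.20, 0.0167), and Lrp2bp (0.96, SE 0.16, 0.0493) rose. Lars2, the mitochondrial leucyl-tRNA synthetase gene, rose from 261 ± 50.4 to 503 ± 50.1 CPM (SD, n = 4 and 3; 0.95, SE 0.15, edgeR adjusted p = 0.0433). Chosen after the values were seen, and the only pair of genes correlated here, its log2 CPM and that of Rn18s were correlated over the 7 libraries (Pearson's r = 0.890, exact permutation p = 0.0113; Spearman's rho = 0.929, exact permutation p = 0.00675), and r was 0.851 without the 2 libraries farthest from the median of Rn18s. With both genes centred by group, the within-group r was 0.827 (exact permutation p = 0.0486 over 144 permutations within groups) and rho 0.857 (exact permutation p = 0.0417). Rn18s itself had a log2 fold change of 0.93 (edgeR adjusted p = 0.367). A rise of Lars2 therefore cannot be told apart from a difference in ribosomal RNA content between the libraries. Bcl6 fell from 124 ± 16.5 to 62.5 ± 2.29 CPM (-0.99, SE 0.10, edgeR adjusted p = 0.00679). Lonrf1 (-0.71, SE 0.09, edgeR adjusted p = 0.0128), Slc16a9 (-0.77, SE 0.11, 0.0249), Tlcd3b (-0.71, SE 0.12, 0.0379) and Cpxm1 (-0.89, SE 0.15, 0.0433) also fell. Dusp7 and Bcl6 stayed past the test without each library in turn, and Zfp503 lost it without AAV8-Null replicate 1 (edgeR adjusted p = 0.0526). Prima1 lost it without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 1 or 3 (edgeR adjusted p 0.0501 to 0.0820), Lonrf1 without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 1 or 2 (0.0550 to 0.0760) and Slc16a9 without AAV8-Null replicate 1 or 2 or AAV8-IGFBP1 replicate 1 or 2 (0.0516 to 0.107). Lars2 lost it without AAV8-Null replicate 1 or 4 or any 1 AAV8-IGFBP1 library (edgeR adjusted p 0.0723 to 0.152), Tlcd3b without AAV8-Null replicate 1 or 3 or any 1 AAV8-IGFBP1 library (0.0931 to 0.1298), Lrp2bp without any except AAV8-IGFBP1 replicate 3 (0.0599 to 0.151) and Cpxm1 without each of the 7 (0.0689 to 0.156).

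Adipocyte markers differed mainly through AAV8-IGFBP1 replicate 2, with a median log2 fold change of 0.88 (18 of 18 above 0, camera adjusted p = 0.00581; adjusted p = 0.805 with an estimated correlation). Ucp1, the uncoupling protein gene of brown fat, picked after its values were seen, reached 123 CPM in AAV8-IGFBP1 replicate 2 and 2.02 to 12.4 CPM in the other libraries. Without AAV8-IGFBP1 replicate 2 the adipocyte median was -0.14 (camera adjusted p = 0.926), and the call was also lost without AAV8-Null replicate 3 (0.0737). By edgeR 0 of the 18 passed, 3 had an unadjusted p under 0.05, DESeq2 called 2, limma-voom called 0, and adjusted over the list alone 0 passed. Macrophage and monocyte markers (median 0.03, camera adjusted p = 0.818), neutrophil and mast cell markers (0.36, 0.818) and the 5 hepatocyte markers with enough counts (0.74, 0.0870) were not called. In edgeR's test 0 of these 22, 12 and 5 markers passed, adjusted over the list alone 0 passed, 1, 8 and 2 had an unadjusted p under 0.05, DESeq2 called 1 in each list and limma-voom 0. The 8 neutrophil and mast cell genes were 4 higher and 4 lower. Among the latter were the mast cell protease genes Tpsb2 (log2 fold change -0.99, SE 0.29, edgeR adjusted p = 0.202) and Cpa3 (-0.89, SE 0.32, 0.305). The median of that list was -0.36 without AAV8-IGFBP1 replicate 2 and 0.69 without AAV8-IGFBP1 replicate 1. Without AAV8-IGFBP1 replicate 3 the macrophage list was called higher (median 0.31, adjusted p = 0.00271), and so was the hepatocyte list without AAV8-IGFBP1 replicate 2 (0.0381) or 3 (0.0145). Alb, the albumin gene and a main liver transcript, had 9 to 46 counts in AAV8-Null and 8 to 40 in AAV8-IGFBP1.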

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

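The tests of explanations for the 3 patterns in this part were chosen only after the results were seen.

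Igfbp1, the gene carried by the liver-directed vector, had 202, 1425 and 142 counts in the quadriceps libraries of AAV8-IGFBP1 replicates 1, 2 and 3. Liver RNA carried into the samples would bring the abundant liver transcripts too, yet in replicate 2 Alb had 8 counts and the hepatocyte markers without Cyp2e1, Trf and Hp summed to 39 against 1425 of Igfbp1, too few to be its source there, although Cyp2e1, Trf and Hp, which other tissues also express, were highest there (3082, 3794 and 2147 counts, against 363 to 1964 in the other libraries). In replicates 1 and 3 they summed to 232 counts against 344, near enough that liver RNA cannot be told apart from other sources there, although the same markers had 36 to 161 counts in AAV8-Null. A swap of the labels would put Igfbp1 in the wrong group, but its lowest CPM in AAV8-IGFBP1 was 16.1 times its highest in AAV8-Null. Transcription of the vector or of the mouse gene in the sampled tissue may be the source. Counts per symbol do not separate these, nor do they show where the 8 counts in AAV8-Null replicate 4 came from. The cells that held the transcript are not known either. AAV8-IGFBP1 replicate 2 also had the highest adipocyte marker level (1.86), while AAV8-IGFBP1 replicates 1 and 3 lay at -0.10 and -0.52.

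Clock genes of the Dbp arm were higher and those of the Arntl arm lower in AAV8-IGFBP1, with medians of log2 fold changes 1.66 apart over the 16 of 20 tested members placed in an arm after the values were seen. AAV8-IGFBP1 replicate 2, the library that stood apart from the rest, did not carry this alone, since the distance was 2.02 without it and the mean level of the Dbp arm minus that of the Arntl arm lay between 0.75 and 1.32 in all 3 AAV8-IGFBP1 libraries and between -1.33 and -0.52 in AAV8-Null. A shift in clock phase may come from the vector or from muscle taken at another time of day in one group. These cannot be told apart, because no time of sampling was given in the sources used here and any difference in it would follow the groups. The same limit holds for any other gene in this comparison that varies with the time of day. Which of the changed genes do so was not tested.

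The medians of interferon response and antigen presentation genes were 0.71 and 0.65, with 3 of 35 and 1 of 19 genes past the test, adjusted p-values of 0.491 and 0.688 with an estimated correlation, and overlapping antigen presentation levels (exact permutation p = 0.0571). Without AAV8-IGFBP1 replicate 2 the interferon median was 0.44 (0.43 with the adipocyte level as covariate), which argues against that library as the whole source, while the antigen presentation median was 0.14 (0.18 with the adipocyte level as covariate), so that most of the latter may come from that library. More macrophages and monocytes would raise their markers too, but the median log2 fold change of those markers was 0.0342 (SD over the markers 0.37), although without AAV8-IGFBP1 replicate 3 they were called higher. Of the 22 markers 11 lay above 0 and 11 below. Ccr2 had 0.86 (edgeR adjusted p = 0.135, DESeq2 0.0229) and Folr2 -0.47 (edgeR adjusted p = 0.559), so a rise in only part of these cells is not ruled out. A response to the vector or its product in muscle stays open as a hypothesis, as do immune cells outside the marker lists.

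Of 217 values tested for a library far from the others among the 4 AAV8-Null libraries, 12 passed Dixon's critical value. Chance gives about 1 in 20, so this count is near that of chance and the values below may be chance extremes. AAV8-Null replicate 4 was the far library in 6 of the 12, with Igfbp1 among the 6. The ratio of 1 for Igfbp1 (log2 CPM -4.49 in replicates 1 to 3 and -2.06 in replicate 4) was fixed by the 0 counts of the other 3 libraries and says nothing about how unusual 8 counts are. In AAV8-Null replicate 4, log2 CPM was 6.52 for Insr (6.31 to 6.34 in the other 3 libraries, ratio 0.851) and 4.74 for Grb10 (4.45 to 4.50, ratio 0.834). The same library had 3.68 for Lonrf1 (3.88 to 3.90, ratio 0.929) and 2.87 for Ier5 (3.49 to 3.54, ratio 0.927). In AAV8-Null replicate 2, log2 CPM was 1.596 for Scx (2.09 to 2.16, ratio 0.875), -0.51 for Higd1b (0.06 to 0.16, ratio 0.845) and 0.04 for Erfe (-0.46 to -0.43, ratio 0.943). Rps6kb1 was at 5.20 in AAV8-Null replicate 1 (5.36 to 5.38, ratio 0.882), and Kera at 3.68 in AAV8-Null replicate 3 (2.41 to 2.53, ratio 0.909). The interferon response level was -0.41 in AAV8-Null replicate 4 (-0.24 to -0.22, ratio 0.863), and the antigen presentation level -0.11 in AAV8-Null replicate 1 (-0.31 to -0.28, ratio 0.866). The AAV8-IGFBP1 group, with 3 libraries, was not tested in this way.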

How the results depend on the processing

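The fits with marker levels as covariates and without both libraries numbered 3 were chosen only after the data were seen. The 34 named genes past the test kept their direction in every alternative run, as did 21 of the 23 lists called in every alternative without a covariate, and 46 of the 125 named genes not past the test passed it in at least 1 alternative. All 87 changed genes had groups that did not overlap. Leaving out a library could therefore hardly reverse a gene, and the kept direction of the genes is weak support. The count of 87 changed genes (58 higher, 29 lower) was 451 with the DESeq2 Wald test (216 higher, 235 lower; 84 shared), which called 47.9% of its genes higher where edgeR called 66.7%. With limma-voom 18 genes were lower. Without a low-count filter 157 genes changed (88 higher, 69 lower), the share higher being 56.1%, and at an adjusted p under 0.10, which by construction calls more, 212 (110 higher, 102 lower). With the slow fibre level as covariate 40 changed, 15 of them higher (37.5%) and 14 shared with the 87, the medians of the IGF axis and clock lists were 0.05 and 0.13, and those of complex I, complexes II to V and the TCA cycle turned from below 0 to 0.07, 0.09 and 0.07. The slow fibre level itself differed by -1.08 between the groups (exact permutation p = 0.0857). This covariate can therefore take up part of the group difference whatever its source, so smaller medians do not show that fibre type explains them. With the adipocyte and tenocyte levels as covariates 70 and 72 changed, 49 and 48 of them shared. Without both libraries numbered 3, with fewer samples, 39 changed (24 higher, 15 lower; 24 shared), and 25 lists were called, 16 of them among the 23. Leaving out 1 library gave 14 (AAV8-Null replicate 1) to 79 changed genes (AAV8-Null replicate 4), 11 to 43 higher and 3 to 36 lower, with fewer samples in each fit. Of the 23 lists called, camera with an estimated correlation called 0, with 4 at an unadjusted p under 0.05, and fry called 1; leaving out 1 library gave 20 to 29 lists. The adipocyte median of 0.88 turned to -0.14 without AAV8-IGFBP1 replicate 2 and was 1.29 without AAV8-IGFBP1 replicate 3, and the tenocyte median of -0.41 turned to 0.26 without both libraries numbered 3. Except for the looser threshold and the fits with fewer samples, the cause was not tested. The libraries held 38947493 to 51210391 counts, so depth limits genes near the floor of 0.0586 to 0.0770 CPM, such as Igfbp1 in AAV8-Null; with this number of libraries 37.2% of simulated 1.5-fold changes were found.

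Libraries with the same replicate number did not deviate together (correlations of -0.10, 0.07 and -0.06 for numbers 1, 2 and 3), and only AAV8-Null replicate 2 correlated best with the AAV8-IGFBP1 library of its own number. These values gave no sign that the numbers pair the samples. Taken over all genes, they cannot exclude a pairing that moved only some genes. With the number as a replicate block, which spends samples on the block, 4 genes changed (3 higher, 1 lower; 1 shared with the fit without it) and 21 lists were called.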

Other observations

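The genes, lists and hypothesis in this part were chosen, and the hypothesis tested, only after the results were seen, and so was the count over other splits of the libraries. Outside the lists and the genes named above, Ifngr2, which encodes a subunit of the interferon-gamma receptor, rose from 64.9 ± 2.17 to 101 ± 5.04 CPM (SD, n = 4 and 3; log2 fold change 0.64, SE 0.06, edgeR adjusted p = 0.00679). Slc7a2, a transporter gene for cationic amino acids (0.78, SE 0.09, 0.00887), the focal adhesion gene Lpp (0.56, SE 0.06, 0.00861) and Chd6 (0.88, SE 0.09, 0.00679) rose too, and these 4 genes stayed past the test without each of the 7 libraries in turn. Fbp2, the fructose bisphosphatase gene of muscle (0.84, SE 0.11, edgeR adjusted p = 0.0167), and Tbc1d4, which regulates glucose transporter traffic (0.41, SE 0.07, 0.0460), rose. With all 7 libraries the list of glycolysis and glucose uptake genes was not called (median -0.07, 8 of 22 above 0, camera adjusted p = 0.165). Acvr1b, an activin receptor gene, also rose (0.58, SE 0.07, edgeR adjusted p = 0.0119). Spon2, a matrix protein gene (-1.86, SE 0.28, edgeR adjusted p = 0.0320), Wdr1, a gene of actin filament turnover (-0.47, SE 0.06, 0.0179), and Ckb, the brain type creatine kinase gene (-0.67, SE 0.11, 0.0381), fell. Acvr1b lost the test without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 1 (edgeR adjusted p 0.0555 to 0.0580), Fbp2 without AAV8-Null replicate 1, 2 or 3 or AAV8-IGFBP1 replicate 2 (0.0502 to 0.0780), and Wdr1 without AAV8-Null replicate 1 or AAV8-IGFBP1 replicate 1 or 2 (0.0732 to 0.0906). Spon2 lost it without AAV8-Null replicate 1 or 3 or any 1 AAV8-IGFBP1 library (edgeR adjusted p 0.0621 to 0.0906), and Tbc1d4 (0.0567 to 0.151) and Ckb (0.0523 to 0.1304) without each of the 7.

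Translation and ribosome biogenesis factors were called higher as a list (median log2 fold change 0.04, camera adjusted p = 0.0285; adjusted p = 0.491 with an estimated correlation), with the elongation factor kinase gene Eef2k at 0.29 (SE 0.06, edgeR adjusted p = 0.0745). Schwann cell and nerve markers were called lower (median -0.24, camera adjusted p = 0.0427; adjusted p = 0.688 with an estimated correlation), with the myelin gene Pmp22 at -0.46 (SE 0.13, edgeR adjusted p = 0.187), and their levels did not overlap between the groups (exact permutation p = 0.0286, two-sided, the smallest that can be given). In edgeR's test 0 of 30 and 0 of 16 members passed, adjusted over the list alone 2 and 0 passed, 4 and 3 had an unadjusted p under 0.05, DESeq2 called 2 in each list and limma-voom 0. The translation call was lost without AAV8-Null replicate 1 (adjusted p = 0.0740, median 0.02) or 4 (0.0677) or AAV8-IGFBP1 replicate 3 (0.0805). The Schwann cell call was lost without AAV8-Null replicate 3 (adjusted p = 0.0827) or 4 (0.1004) or AAV8-IGFBP1 replicate 3 (0.227), and the median was -0.41 without AAV8-IGFBP1 replicate 2. Of the noncoding RNAs, 7SK (log2 fold change 0.71, SE 0.12, edgeR adjusted p = 0.0460) and Metazoa_SRP, the signal recognition particle RNA (0.76, SE 0.12, 0.0433), had higher counts, as symbols that cover many copies. Rn18s was at 0.93 (SE 0.36, 0.367), while H19 (-0.71, 0.0307) and mt-Rnr2 (-0.49, 0.254) went the other way. With all 7 libraries the list of nuclear-retained long noncoding RNAs was not called (median 0.06, camera adjusted p = 0.333). The libraries were made with an mRNA-Seq kit, and whether library preparation moved the counts of these RNAs was not tested. 7SK lost the test without each of the 7 libraries (edgeR adjusted p 0.0689 to 0.144) and Metazoa_SRP without AAV8-Null replicate 1 or 3 or any 1 AAV8-IGFBP1 library (0.0895 to 0.144).

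Socs2, Igfals and Igfbp5 rose and Bcl6 fell, and Socs2, Igfals and Bcl6 are known to respond to growth hormone through STAT5 in liver, so a stronger growth hormone and STAT5 response in muscle may be proposed as a hypothesis. The mean level of 7 other STAT5 targets did not differ beyond the spread (exact permutation p = 0.6, two-sided). Cish had a log2 fold change of 0.89 (SE 0.88, edgeR adjusted p = 0.740), and the other 6 had values below 0, with Pim1 at -1.003 (SE 0.30, 0.263) and a median over the 7 of -0.64 (SD 0.84). Cish lay at 28.4 to 38.6 CPM in AAV8-IGFBP1. In AAV8-Null it lay at 4.70 to 7.65 CPM in replicates 1, 3 and 4 but at 48.6 in replicate 2. Igf1, which was not among the 7, had a log2 fold change of 0.60 (edgeR adjusted p = 0.177) and groups that did not overlap. With so few targets and so wide a spread, the hypothesis stays open.

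For the counts of genes, only the real split reached the real value. That share of 1 of 35 is under 0.05 and is the smallest this design can give. It argues against chance in how the 7 libraries were grouped but cannot exclude it. Every other split mixed AAV8-Null and AAV8-IGFBP1 libraries on a side, which can lower its count where the groups differ. The real split, 1 of 35, gave 87 changed genes and the highest other split 7; it gave 58 higher genes against at most 4 in the others, and 29 lower against at most 3, so that only 1 split reached each count. The count of lists does not argue against chance, since 7 of the 35 splits gave at least as many as the real 23 and the highest other gave 28.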
